A study of Rattus norvegicus with 2 samples.

How the data were processed

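Leukocytes were isolated from left ventricles of rats with a myocardial infarction, infarct and border zone together, by enzymatic digestion, red blood cell lysis and fluorescence-activated sorting of cells stained for CD45, with propidium iodide as a stain for dead cells, per the labels' protocols. Libraries were made with the 10x Genomics Chromium platform, which tags each captured transcript end with a cell barcode and a UMI, and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The deposited matrix holds raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 per the file headers. The genome build, the annotation and the settings for calling cells are not given in the sources used here. The matrix lists 32623 genes and 29949 barcodes with 155309082 UMIs in all. Counts of the 1453 symbols on more than 1 line were added up, which left 26976 symbols.

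The labels give 1 sample to each of the groups MI and MI+PUR-hAESC. The matrix pools both samples, and its barcodes end in suffix 1 or 2. A deposited table of 33756 barcodes names libraries of its own, but only 111 of its barcodes are in the matrix with the same suffix, and its barcode sets shared 47 to 64 barcodes with each library of the matrix, against 71 shared by the 2 libraries of the matrix themselves. It therefore describes other cells and was not used to assign any. Neither suffix can be tied to a group, so the planned comparison of the groups could not be made. Values are given per library, and log2 ratios are library 2 over library 1, with no treatment behind the direction.

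Barcodes with at least 200 genes and at most 20% mitochondrial UMIs passed, which left out 315 of library 1 and 235 of library 2. Scrublet was run per library with an expected share of 8%. It called 629 doublets (4.50%) in library 1 and 1210 (7.84%) in library 2, which were left out. Its score cut-off was 0.2777 in library 1 and 0.2129 in library 2, and equal cut-offs were not tried. The 27560 kept cells were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes and 30 principal components, joined through 15 nearest neighbours and clustered with the Leiden method at resolution 1, without alignment of the libraries. This used scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

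Clusters were named from marker lists of 20 cell types and states fixed before the data were examined. The rule for using them was set after the clusters were seen and was revised 2 times for the clusters with Rag1 or Dntt. A cluster took the class with the most markers at 2-fold or more over other cells and 20 CPM or more. At least 3 had to pass, and the mean log2 fold over all measured markers of the list had to be above 0. The runner-up had to have under 0.75 times as many passing markers. A cluster also stayed unnamed where another list had more of its 10 leading genes. The same held where its cells' median UMI number was under 33.3% of that of their library with no own marker among those genes. No cluster fell under this limit (macrophage-like cluster 14, with no own marker among its leading genes, stood at 0.393 times). Clusters nearest to T cells with Rag1, Ptcra or Dntt among the 10 leading genes were set apart as Rag1-led. This named 10 classes in 19 clusters, with 2 Rag1-led and 7 unnamed clusters. Classes were made from the same counts, so differences between classes were not tested.

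Raw counts were summed per library and class with 200 or more cells in each library and divided by their total to CPM. Ratios are log2 of CPM plus 10. For each of 28 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 CPM in either library, in the classes the list is about. The interval of a median comes from 2000 Poisson draws of the counts, and its place was described among 10000 random lists matched on expression. Sex-linked genes are named where detected, but Xist and Uty were not among the genes of the matrix. Other named genes were chosen by a rule fixed before the data were examined. Among genes with at least 50 UMIs and 50 CPM in the higher library and a proper symbol, without mitochondrial, ribosomal, haemoglobin and receptor segment genes, it takes the 12 highest and 12 lowest ratios in the class with the most cells and 6 of each in other classes. Of each list, up to 4 members at 50 CPM or more serve as examples. Values of some genes that the rules name are not reported here. A class with 1 library on each side gives no test, so no p-value was computed. The Poisson intervals of both libraries lay apart for 96 of the 96 named genes, which were chosen for their size. For the list examples they lay apart in 542 of 771 values and overlapped in 229.

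For shares of cells with a UMI or dividing cells, each cell was thinned at random to 1500 UMIs, which left out 795 cells of library 1 and 939 of library 2 that held fewer. A cell counted as dividing with at least 2 UMIs over the proliferation list. Shares have exact Clopper-Pearson intervals and CPM values exact Poisson intervals, at 95%. A count of 0 allows up to 3 counts, which is 0.0225% of the kept cells of library 1 and 0.0211% of library 2.

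The steps were tested on simulated data for the largest cluster: 200 genes among 26976 were changed by known folds in Poisson counts at the real depth. Within 0.5 log2 units of the set value were 50 of 50 genes at 2-fold, 50 of 50 at 4-fold, and 1901 of 1902 unchanged genes. A simulated 2-fold list of 20 genes gave a median of 0.91.

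Alternatives covered the cell filter, doublets kept, resolutions 0.5 and 2, each library clustered alone, class by each cell's own markers, TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, ribosomal and haemoglobin genes, a pseudocount of 1 CPM, no minimum level, a minimum of 200 CPM, a mean over clusters, thinning, and other counts for dividing cells. With doublets kept, all passing cells were clustered and named anew, into 35 clusters. Class membership therefore changed too, and a move under this setting cannot be laid to the doublets alone. Leaving the Rag1-led clusters out of the denominator was added after the data were seen.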

Results

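The series profiled immune cells of the infarcted rat heart, sorted by the leukocyte surface protein CD45 from left ventricles 7 days after surgery. Per the labels, 1 library came from hearts with a myocardial infarction (MI) and 1 from infarcted hearts covered with a patch (MI+PUR-hAESC), a polyurethane scaffold that carries human amniotic epithelial stem cells. The question of the series was what the patch does to the immune cells of the heart. The deposited matrix holds 2 libraries that differ in their barcode suffix, called library 1 and library 2 here. No source used here ties a suffix to a group, so the values of both libraries stand side by side and no difference between them is read as an effect of the patch.

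Library 1 held 14283 barcodes and 72506643 unique molecular identifiers (UMIs), with a median of 3692 UMIs and 1483 genes per barcode. Library 2 held 15666 barcodes and 82802439 UMIs, with a median of 4367.5 UMIs and 1655 genes. After filtering and removal of called doublets, 13339 cells of library 1 and 14221 of library 2 were kept and clustered together into 28 clusters. There is 1 library per group and no replicate, so no difference was tested. Intervals in parentheses are 95% intervals, exact for shares and CPM values and from Poisson draws of the counts for list medians. They cover counting error only.

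Neutrophil-like, macrophage-like and lymphocyte-like cells made up most of both libraries, in different proportions. Neutrophil-like cells, marked by S100a8, S100a9, Csf3r and Il1r2, made up 32.2% of library 1 (31.5 to 33.0) and 12.5% of library 2 (11.99 to 13.1). T-like cells, with Cd3e of the T cell receptor complex, made up 11.9% (11.4 to 12.5) and 19.7% (19.1 to 20.4). B-like cells, with Cd79b and Ms4a1, made up 6.37% (5.96 to 6.80) and 12.9% (12.4 to 13.5), and NK-like cells 9.12% (8.63 to 9.62) and 13.5% (12.98 to 14.1). Of the NK-like clusters, cluster 2, with Ncr1 and Klrb1a among its leading genes, held 7.35% and 9.39%. Cluster 18, with Gzma and Prf1, held 1.48% and 1.23%, and cluster 17, with Fcrl6, Sept5 and Ccl1, held 0.285% and 2.93%. Macrophage-like cells, with the complement genes C1qa, C1qb and C1qc, made up 17.4% (16.8 to 18.1) and 15.3% (14.7 to 15.9).

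Monocyte-like cells, led by Fcnb, Thbs1 and Vcan, made up 5.20% of library 1 (4.82 to 5.59) and 2.61% of library 2 (2.35 to 2.88). Only 7 of the 12 monocyte markers were measured, without Ccr2, Plac8, Ly6c, Chil3 and Treml4, so monocytes in unnamed clusters could be missed. Unnamed cluster 7, for which no list was clearly ahead, held 3.25% of library 1 and 6.72% of library 2. Conventional dendritic-like cells, led by Ccl17, Cst3, Flt3 and the class II genes RT1-Da and RT1-Ba, made up 3.15% (2.86 to 3.46) and 2.53% (2.28 to 2.80). The haemoglobin gene Hba-a2 was also among their leading genes, but 2 cells per library held most of its 10836 and 6414 UMIs there, with 455 and 336 in the other 418 and 358 cells. Plasmacytoid dendritic-like cells, led by Siglech and Irf8, made up 0.457% (0.350 to 0.587) and 0.352% (0.261 to 0.463), and mast cell- or basophil-like cells, led by Mcpt2, Cma1 and Cpa3, numbered 13 and 9. All shares depend on the CD45 gate, the dissociation and the red blood cell lysis. A group of clusters led by Rag1 or Dntt held 6.91% of library 2 (6.50 to 7.34) and 1 cell of library 1, which lowers the other shares of library 2. The 7 clusters that no marker list named held 13.8% of library 1 (13.2 to 14.4) and 13.5% of library 2 (12.97 to 14.1).

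**Figure D1:**
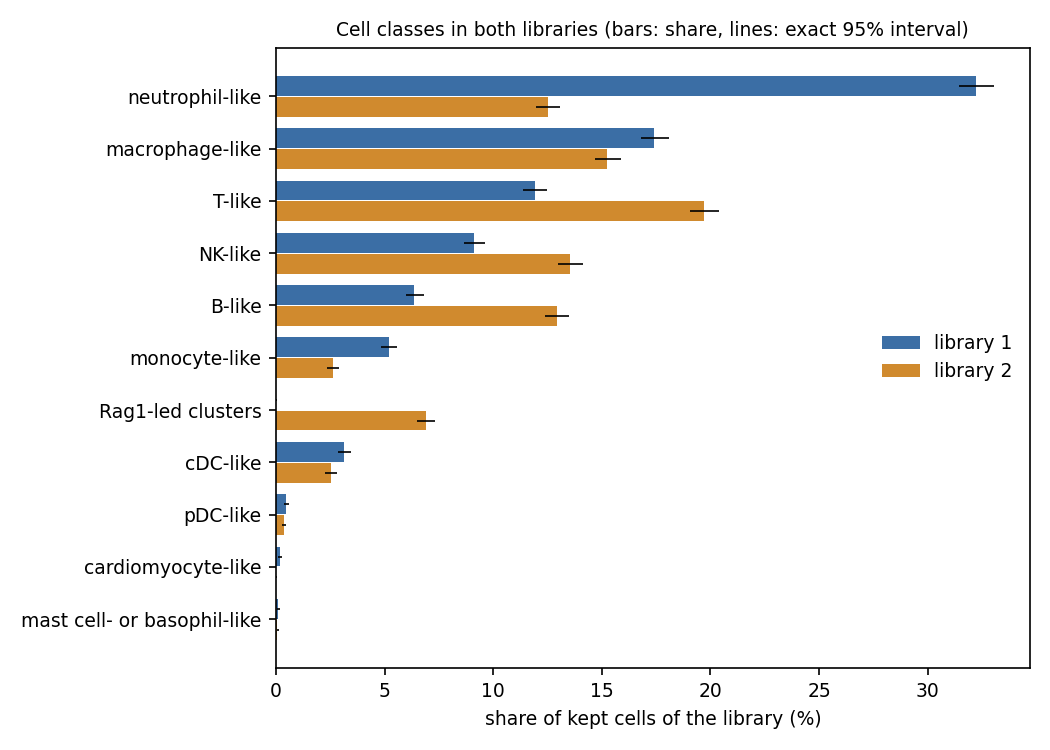
Share of kept cells in each cell class (horizontal axis, percent) for library 1 (blue) and library 2 (orange); bars give the share and black lines its exact 95% interval. The neutrophil-like bar is the longest of library 1 at 32.2%, the T-like bar the longest of library 2 at 19.7%, and the Rag1-led bar is visible in library 2 alone, at 6.91%.

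The Rag1-led cells of library 2 expressed genes of developing lymphocytes. They formed a cluster of 862 cells with a median of 1617.5 UMIs and a cluster of 121 cells with 7796 UMIs, whose leading genes include those of cell division. Rag1, which cuts receptor genes during their rearrangement, stood at 1002 CPM (964 to 1040) in these cells against 0.570 CPM in T-like cells of library 2. Dntt, which adds bases at the joints, stood at 715 CPM (683 to 747), and Ptcra, the surrogate alpha chain of the immature T cell receptor, at 254 CPM (235 to 273). Thinning left out 336 of the 983 Rag1-led cells, against 41 of 2804 T-like cells of library 2. At 1500 UMIs per cell, 84.7% of the other 647 had a Cd8a UMI (81.7 to 87.4) and 77.6% a Cd3e UMI (74.2 to 80.7). As a background in library 2, these shares were 1.79% and 1.79% in B-like and 2.82% and 1.90% in neutrophil-like cells. UMIs of both Cd4 and Cd8b were in 26.4% of the 647 Rag1-led cells (23.1 to 30.0). The share with UMIs of both Cd4 and Cd8b was 0.0724% in T-like cells of library 2 (0.00877 to 0.261). Without thinning these shares were 88.9%, 86.0% and 34.5% in the Rag1-led cells, at a median of 1676 UMIs, and 0.820% for both Cd4 and Cd8b in T-like cells, at a median of 4907. Since Rag1 and Dntt define these clusters, their level is a description of the clusters and not a comparison.

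Macrophage-like cells of library 2 held more transcripts of interferon-response genes, and those of library 1 more of genes for lipid handling and matrix. Of the 18 members of the type I interferon list above the minimum, 18 were higher in library 2, with a median log2 ratio of 0.84 (0.78 to 0.93), which was at percentile 100 of random lists matched on expression. Irf7, a transcription factor of the interferon response, stood at 49.0 CPM (45.9 to 52.3) in library 1 and 229 CPM (221 to 236) in library 2, and the chemokine gene Cxcl10 at 14.6 and 55.2 CPM. All 13 members of the interferon gamma and class I presentation list were higher in library 2 (median 0.82), among them Gbp2 with 33.6 and 88.2 CPM. The class II presentation list had 6 of 8 members higher in library 2 (median 0.46, or 0.10 as a mean over clusters), with RT1-Bb at 163 and 301 CPM.

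The lipid-handling and Trem2 list had 14 of 16 members higher in library 1 (median -0.61, -0.62 to -0.59). Spp1, which encodes osteopontin, stood at 4308 CPM in library 1 and 1549 in library 2, and Lgals3, which encodes galectin-3, at 1759.5 and 1068. Of the matrix remodelling list, 14 of 17 members were higher in library 1 (median -0.62), while the protease gene Ctss stood at 329 and 483 CPM, and of the glycolysis list 13 of 14 (median -0.29), with Ldha at 1012 and 719.7 CPM. The reparative and resident macrophage list had 13 of 16 members higher in library 1 (median -0.23, or -0.39 with doublets kept), including the scavenger receptor gene Cd163 with 50.3 and 15.1 CPM and Arg1 with 58.0 and 18.3 CPM. Spp1 and Arg1 also lead macrophage-like cluster 8, with 762 cells of library 1 and 344 of library 2. As a mean over clusters weighted alike in both libraries, the medians were -0.23 for the lipid list, -0.35 for the matrix list and -0.13 for glycolysis, and the log2 ratio of Spp1 was -0.72 in place of -1.47. The class also holds cluster 14, led by Cideb and the immediate early gene Jun, with a median of 11.9% mitochondrial UMIs, and cluster 19, led by cell division genes.

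In macrophage-like cells, antioxidant and NRF2 target genes had 16 of 21 members higher in library 1 (median -0.19), with Prdx5 at 2712 and 1449 CPM and Hmox1 at 294 and 194 CPM, while Nfe2l2 stood at 159 and 186 CPM. Oxidant production genes had 5 of 6 members higher in library 2 (median 0.10), with Cybb at 1664 and 1945 CPM. Pro-inflammatory cytokines went both ways (median -0.05), with Ccl12 at 70.8 and 164 CPM and Cxcl3 at 179 and 62.7 CPM. With doublets kept and all cells clustered anew, the log2 ratio of Cxcl3 was -0.33 in place of -1.38. Efferocytosis genes, for the uptake of dead cells, also went both ways (median -0.13), with Axl at 51.7 and 95.4 CPM and Gas6 at 137 and 116 CPM. All 10 cell cycle members were higher in library 2 (median 0.51, or 0.14 as a mean over clusters).

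Monocyte-like and dendritic-like cells showed the same side for interferon genes. In monocyte-like cells all 20 type I interferon members were higher in library 2 (median 1.14, 1.03 to 1.19), with Mx1 at 63.7 and 241 CPM, and all 15 interferon gamma members (median 0.74). Their matrix list was higher in library 1 in 10 of 12 members (median -0.48, or -0.21 with no minimum), with Thbs1 at 796 and 175 CPM and Timp1 at 376 and 139 CPM. The unfolded protein response list was higher in library 1 in 9 of 13 members (median -0.57, or -0.22 with no minimum), with Xbp1 at 65.3 and 24.9 CPM. In conventional dendritic-like cells 18 of 19 type I interferon members were higher in library 2 (median 0.71, 0.59 to 0.80), with Irf7 at 38.7 and 102 CPM. These cells had a median doublet score of 0.096 at 12212 UMIs, and the cut-off for doublets was higher in library 1. Transcripts of other cell types did not all go the same way in them, and Rag1 had 0 UMIs in library 1 and 24 in library 2. Lower in library 2 were the neutrophil genes S100a9 at 444 and 149, S100a8 at 193 and 69.3 and G0s2 at 108 and 27.6 CPM and the macrophage gene Apoe at 463 and 87.1 CPM. These log2 ratios with doublets kept were -0.88 for S100a9 in place of -1.52, -0.70 for S100a8 in place of -1.36 and 0.55 for Apoe in place of -2.29. TMM scaling shifted monocyte-like log2 ratios by -0.12, the only class with a shift over 0.1.

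Neutrophil-like cells of the 2 libraries came mostly from different clusters. Cluster 0, led by Il1r2, G0s2, Ptgs2 and Il1b, held 3546 cells of library 1 and 520 of library 2, and cluster 5, led by Retnlg, Isg15, Ifit3, Mmp8 and S100a9, held 755 and 1262. Over the whole class, 8 of 9 pro-inflammatory members were higher in library 1 (median -0.75, or -0.27 as a mean over clusters), with the chemokine genes Cxcl3 at 422 and 92.2 CPM and Cxcl1 at 203 and 44.7 CPM. As a mean over clusters, the log2 ratio of Cxcl3 was -0.41 in place of -2.08 and that of Cxcl1 -0.88 in place of -1.96. The type I interferon list had 17 of 19 members higher in library 2 (median 0.63, or 0.22 as a mean over clusters). Within cluster 0 its median was 0.50 and within cluster 5 it was -0.09. Antioxidant genes were higher in library 2 in 11 of 16 members (median 0.29, or 0.10 as a mean over clusters), with Sod2 at 3415 and 5663 CPM and Gpx1 at 2172 and 1233 CPM.

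Lymphocyte-like classes shared the side of the interferon list. The median log2 ratio was 0.50 (0.39 to 0.56) in T-like cells with 15 of 17 members higher in library 2, 0.49 (0.39 to 0.57) in NK-like cells with 15 of 18, and 0.31 (0.22 to 0.44) in B-like cells with 14 of 15. Isg15 stood at 97.1 and 205 CPM in T-like cells and at 62.9 and 149.9 CPM in NK-like cells, and Ifi27 at 225 and 631 CPM in B-like cells. Bst2 went the other way in T-like cells, with 344 and 319 CPM. Apoe, a macrophage transcript, was lower in library 2 in T-like (409 and 114 CPM), NK-like (317 and 125 CPM) and B-like cells (839.9 and 288 CPM). Of 12 genes that respond to TGF-beta, those above the minimum were lower in library 2 in 5 of 6 cases in T-like (median -0.54, or -0.21 with no minimum), 5 of 5 in NK-like (-0.36, or -0.14) and 4 of 5 in B-like cells (-0.34, or -0.13). In these classes, Pmepa1 stood at 217 and 106, 196 and 107, and 269 and 146 CPM. Tgif1 went the other way in B-like cells, with 159.6 and 202 CPM, and stood at 95.9 CPM in both libraries in T-like cells. Cytotoxic genes differed little as a list in T-like cells (median -0.01), with Prf1 at 339 and 241 CPM and Ifng at 66.7 and 103 CPM. In NK-like cells 10 of 13 of them were higher in library 1 (median -0.19), with Gzmk at 1663 and 898 CPM.

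Immediate early and stress genes, which tissue dissociation can raise, differed between the libraries in several of the classes whose interferon list differed. Their list was higher in library 2 in 16 of 16 members in NK-like cells (median 0.32, or 0.16 as a mean over clusters), with Egr1 at 93.3 and 161 CPM and Nr4a1 at 134 and 224 CPM. In B-like cells 15 of 16 members were higher in library 2 (median 0.21), with Fos at 744 and 1134 CPM. The count was 14 of 18 in macrophage-like cells (median 0.20, or 0.10 as a mean over clusters and 0.09 with doublets kept), with Zfp36 at 352 and 552 CPM. It was 13 of 17 in conventional dendritic-like (median 0.22) and in monocyte-like cells (0.13, or 0.37 with doublets kept and 0.029 with TMM), and 9 of 16 in T-like cells (0.03). In neutrophil-like cells 14 of 17 members were higher in library 1 (median -0.16, or -0.090 as a mean over clusters and -0.31 with no minimum), with Ier3 at 649 and 312 CPM.

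**Figure D2:**
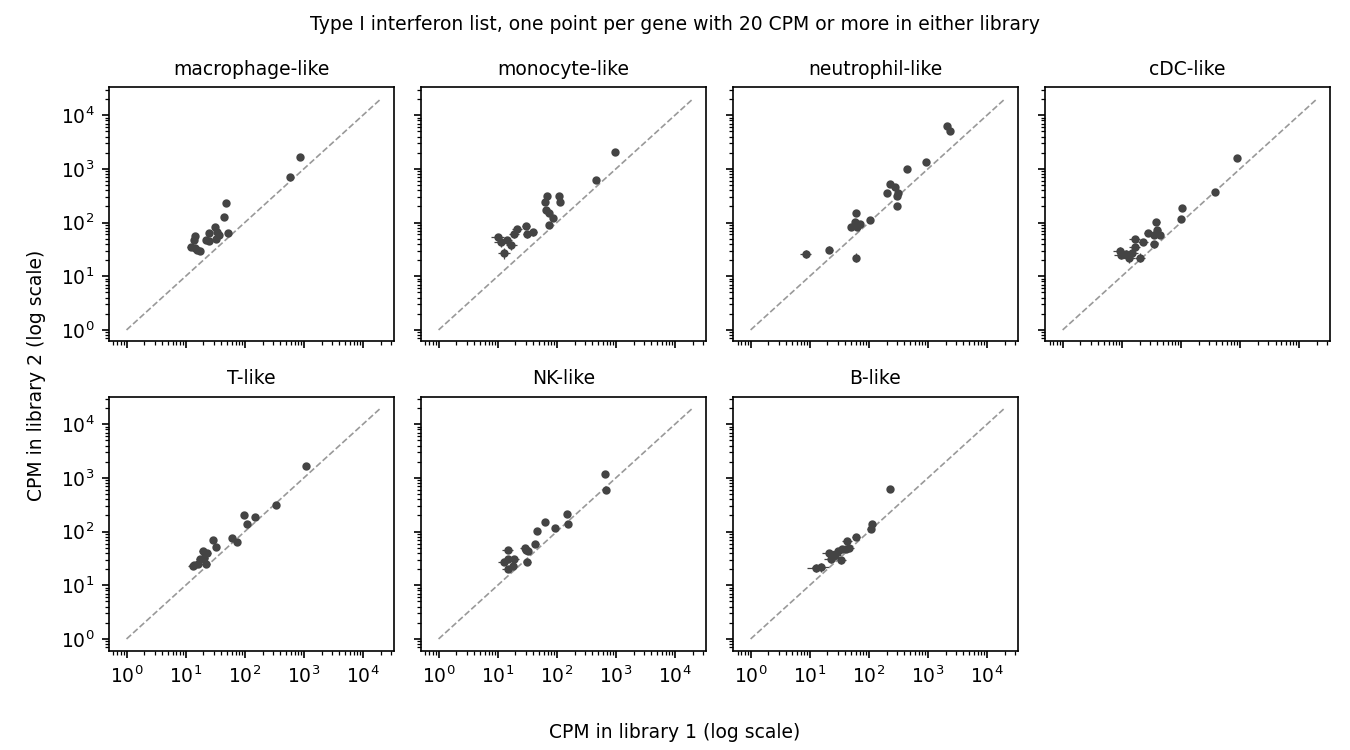
Type I interferon list in 7 cell classes; each point is 1 gene with 20 CPM or more in either library, with its CPM in library 1 (horizontal, log scale) and library 2 (vertical, log scale), lines for exact 95% Poisson intervals and a dashed line for equal values. In macrophage-like and monocyte-like cells all 18 and all 20 points lie above the dashed line; in neutrophil-like cells 17 of 19 do.

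Cluster 10, led by Tnfrsf4, Il17a, Il2ra, Foxp3 and Gata3, held 511 cells of library 1 and 461 of library 2 and was left unnamed because a gene of the innate lymphoid list was among its leading genes. Of its regulatory T cell list, 10 of 12 members were higher in library 2 (median 0.38), with Foxp3, the lineage factor of regulatory T cells, at 52.0 and 123 CPM. Of its helper list 5 of 9 members were higher in library 1 (median -0.68), with the interleukin gene Il17a at 214 and 125 CPM and the chemokine receptor gene Ccr6 at 136 and 48.8 CPM. Foxp3, Il17a and Gata3 also define the cluster, so these values describe its content in each library. Myeloid transcripts were lower in library 2 in the same cluster, with S100a9 at 519.5 and 120.1, S100a8 at 192 and 61.7 and Apoe at 1352 and 146 CPM. Cluster 7 (434 and 955 cells), led by Mal, Adgre4 and Eno3, had a type I interferon median of 0.32 and a class II median of -0.64, with Apoe at 846 and 140.2 CPM. Cluster 16 (227 and 282 cells), led by Klra22 and genes of the Ly49 family, had a type I interferon median of 0.27.

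Dividing cells were counted from genes of DNA synthesis and mitosis at 1500 UMIs per cell. At this depth T-like cells held the largest share among the named classes, 13.8% in library 1 (12.1 to 15.5) and 16.2% in library 2 (14.9 to 17.6). In macrophage-like cells the share was 7.77% (6.67 to 8.98) and 10.3% (8.96 to 11.7), in NK-like cells 3.61% (2.62 to 4.83) and 6.68% (5.60 to 7.90), and in conventional dendritic-like cells 2.95% (1.53 to 5.09) and 7.41% (4.90 to 10.7). B-like cells had 5.46% (4.01 to 7.24) and 5.04% (4.07 to 6.16). Neutrophil-like cells, which no longer divide, had 1.59% (1.22 to 2.03) and 1.72% (1.14 to 2.47), which serves as the background. At this depth monocyte-like cells did not rise above it, with 1.02% (0.411 to 2.09) and 0.809% (0.167 to 2.34). The Rag1-led cells of library 2 had 44.5% (40.6 to 48.4) among the 647 that held 1500 UMIs or more, and 43.7% without thinning among all 983. Without thinning, conventional dendritic-like cells had the largest share among the named classes, 29.8% and 37.8%, at median depths of 12382 and 12050 UMIs. The shares were then 28.1% and 33.3% in T-like, 18.6% and 23.8% in macrophage-like, 16.8% and 24.9% in NK-like, 14.4% and 13.8% in B-like, 5.77% and 9.97% in monocyte-like and 2.91% and 5.67% in neutrophil-like cells. The median depths of these 6 classes were 4491 and 4907, 7654 and 6592.5, 4339.5 and 4696, 2891.5 and 2773.5, 7910 and 7554, and 2215 and 2524.5 UMIs.

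UMIs counted under the haemoglobin gene Hba-a2 were found in conventional dendritic-like cells, with 2 and 14 beta-globin UMIs beside them, and counts per gene do not show which transcript they came from. At 1500 UMIs per cell, and with 2 such cells per library left out for erythroid genes or 50 or more haemoglobin UMIs, 8.89% of them in library 1 (6.30 to 12.1) and 9.74% in library 2 (6.84 to 13.3) had an Hba-a2 UMI. The share in T-, B-, NK- and neutrophil-like cells together was 0.463% (0.323 to 0.643) and 1.44% (1.19 to 1.72). Without thinning the shares were 39.7% and 39.9% in conventional dendritic-like cells, at median depths of 12354.5 and 12096 UMIs, and 0.741% and 3.56% in the other 4 classes, at 2731 and 3862 UMIs. Hba-a2 was also a leading gene of unnamed cluster 15, with 393 cells of library 1 and 129 of library 2. The beta-globin gene Hbb and the myeloid transcripts Spp1 and Apoe led that cluster too, and it is not part of these shares.

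**Figure D3:**
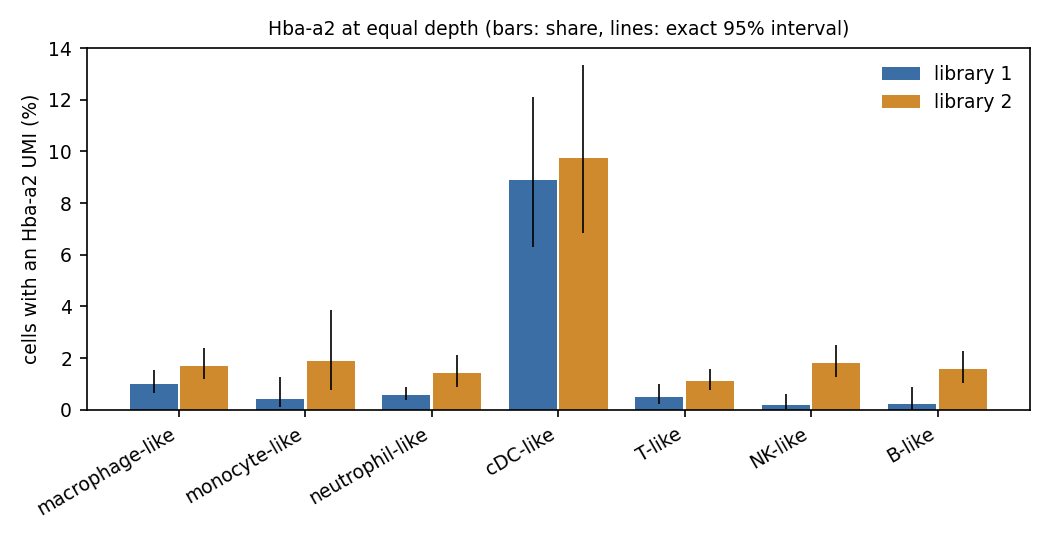
Percent of cells with an Hba-a2 UMI after thinning to 1500 UMIs (vertical axis) in 7 cell classes of library 1 (blue) and library 2 (orange), with exact 95% intervals as lines. Conventional dendritic-like cells stand at 8.89% and 9.74%, and the intervals of the other classes drawn lie below both. Unnamed cluster 15, also led by Hba-a2, is not drawn.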

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

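The tests of free RNA, doublets and B cell precursors were chosen after the Rag1-led clusters were seen, and the 7-gene test was fixed before those genes were looked up in them, although Ccl5 was already known to lead a T-like cluster. Data outside the planned comparison drew attention in 3 places: cells with a Rag1 UMI, cells of non-immune type behind a CD45 gate, and a barcode table of other cells.

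Among all deposited barcodes, 952 of library 2 had a Rag1 UMI and 0 of 14283 of library 1, which allows a share of barcodes with such a UMI of up to 0.0210% there. Cells that express Rag1 can lack a UMI of it, as only 74.6% of the Rag1-led cells of library 2 had one without thinning. Rag1 marks lymphocytes that are still rearranging their receptor genes, which happens in thymus and bone marrow. Of 7 genes that set cortical thymocytes apart from mature T cells, Arpp21 (671 CPM against 89.98 in T-like cells of library 2), Satb1 (1062 against 164), Klf2 (7.66 against 30.8), Il2rb (19.7 against 151) and Ccl5 (505 against 12005) differed in the stated direction by at least 2-fold. Aqp11 (0 against 0.0633) lay near the floor and did not pass.

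Free RNA would spread Rag1 and Dntt UMIs over cells independently, while at equal depth 289 cells of library 2, in any cluster, had UMIs of both, 17.4 times the number expected from the single shares. B cell precursors would carry Cd79b, which 1.38% of these 289 cells had (0.378 to 3.51), against 75.8% with Cd3e (70.4 to 80.6). Doublets would hold more UMIs and score higher as doublets than T-like cells of library 2 (medians 4907 and 0.0214), and the cluster of 862 cells held 0.330 times as many UMIs at a score of 0.0113, but the cluster of 121 cells, at 7796 UMIs and 0.0868, stays open, since its UMIs were 0.892 times those of the dividing T-like cluster and its score was close to the 0.0812 there. Thymocytes among the sorted cells may be the source, a hypothesis for which 5 of the 7 genes were needed and 5 were found, some of which are also low in naive T cells. Whether they came from thymus left on the heart, from blood or from the ventricle was not tested, and no biological explanation by group was tested because the libraries carry no group.

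The cluster with endothelial and fibroblast genes (Cdh5, Col3a1, Col1a1, Sparc) held 187 cells of library 1 and 57 of library 2. A CD45 gate should hold few such cells. Cardiomyocyte-like cells, led by Tnnt2, Mb and Tnni3, numbered 24 in library 1 and 2 in library 2. The deposited barcode table lists 33756 barcodes that describe cells outside the matrix, and those cells were not analysed here.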

How the results depend on the processing

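The alternative without the Rag1-led clusters in the denominator was chosen after the data were seen; the others were planned. No replicate exists, so a result counts as moved when it left its own counting interval and as reversed when it changed sign while that interval excluded 0. No paired analysis was possible because each group has 1 library and neither library is tied to a group. Neutrophil-like shares stayed at 31.6% to 33.2% in library 1 and 12.3% to 13.5% in library 2. Library 2 had the smaller neutrophil-like and the larger T-like share under every alternative run, and the smaller macrophage-like share too.

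In library 1 and library 2, the T-like share was 9.88% and 15.5% with all deposited cells, 11.2% and 18.1% with doublets kept, 15.4% and 23.1% at resolution 0.5, 14.6% and 22.9% with libraries clustered alone and 16.5% and 29.9% by each cell's own markers. At resolution 2 it was 16.6% in library 2. The macrophage-like share was 14.2% and 12.2% with all cells, 13.1% and 11.99% under the stricter filter, 14.5% and 13.1% with doublets, 13.8% and 12.2% at resolution 0.5, 15.1% and 14.5% at resolution 2, 16.2% and 11.1% clustered alone and 19.4% and 15.97% by own markers. The neutrophil-like share was 33.2% in library 1 under the stricter filter and 13.2% in library 2 by own markers. Clustered alone, Rag1-led cells made up 0% and 6.13%. Without them in the denominator, library 2 had 21.2% T-like, 16.4% macrophage-like and 13.5% neutrophil-like cells. The cause of these moves was not tested, except that leaving cells out of the denominator raises every other share.

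In macrophage-like cells the interferon median was 1.03 with a pseudocount of 1, 0.75 with no minimum, 0.68 with doublets and 0.72 as a mean over clusters. The lipid-handling median was -0.68 with TMM, -0.55 with doublets, -0.58 with thinning and -0.23 as a mean over clusters. The interferon list was above 0 in 46 of 46 values over 7 classes (0.22 to 1.23).

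Reversed medians reached at most 0.22 in size. With no minimum these were oxidant production in B-like (0.013), pro-inflammatory genes in macrophage-like (0.028) and monocyte-like (0.0092), and growth factors in macrophage-like cells (0.0012). With doublets kept they were lipid-handling (0.11) and class II genes (-0.093) in dendritic-like cells, and pro-inflammatory (0.0076) and hypoxia genes (0.032) in macrophage-like cells. With TMM it was antioxidant genes in monocyte-like cells (-0.027). As a mean over clusters they were cell cycle in T-like cells (-0.11) and, in neutrophil-like cells, reparative and growth factor genes (0.012 each), lipid-handling (0.22), glycolysis (0.060), hypoxia (0.090) and NF-kB genes (0.066). With doublets kept, Ccl4 in B-like (-0.10) and Apoe in dendritic-like cells (0.55) reversed. The cause was not tested. Of 143 list medians 96 kept their sign under every alternative run for them, as did 94 of 96 named genes. The mean over clusters was run for 85 of the 143 medians and 60 of the 96 genes, and the minimum of 200 CPM for 36 of the genes. The depth of small classes limits lists with few members over 20 CPM.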

Other observations

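The tests of free RNA of neutrophil-like cells, of depth and of cluster make-up, and those on Hba-a2, were all chosen after the results were seen. The genes listed below as higher in either library of a class follow the naming rule, and the direction is that of unlabelled libraries. Apoe follows it in the classes where it had the lowest ratio. The sex-linked genes, Hba-a2, members of the interferon list and genes given as checks or for comparison were not chosen by this rule.

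Fam111a, linked to the restriction of viral replication, had the highest ratio among the genes the rule allows in 4 of 7 classes. It had 5.44 CPM in library 1 and 92.9 in library 2 in macrophage-like, 13.9 and 143 in T-like, 1.80 and 76.9 in NK-like and 1.67 and 52.7 CPM in conventional dendritic-like cells. In B-like (0.389 and 30.0 CPM), monocyte-like (0.706 and 33.1 CPM) and neutrophil-like cells (0.298 and 5.28 CPM) it stayed under the 50 CPM that the rule asks for. Unnamed clusters 7 (0 and 20.6 CPM), 10 (0.80 and 64.2 CPM) and 16 (3.91 and 88.9 CPM) had more of it in library 2 too. The difference was therefore one between the libraries and not particular to the 4 classes, and its cause was not tested. In macrophage-like cells library 2 also had more Fcgr3a, an antibody receptor gene (112 and 440.4 CPM), Slfn4 (326 and 1112 CPM), Ifi27l2b (313 and 1131 CPM) and Ly6e (275 and 840.0 CPM). Library 1 had more Ccl24, a chemokine that attracts eosinophils (702 and 223 CPM), Dmkn (56.6 and 1.82 CPM), Vcan (392 and 139 CPM) and Cxcl3 (179 and 62.7 CPM). With doublets kept and all cells clustered and named anew, the log2 ratio was -0.21 for Ccl24, -0.09 for Dmkn, -0.93 for Vcan and -0.33 for Cxcl3. Dmkn and Ccl24 lead cluster 8. In monocyte-like cells library 1 had more Slpi, an inhibitor of neutrophil elastase (7220.5 and 1637 CPM), Ltb4r, the leukotriene B4 receptor gene (83.5 and 3.07 CPM), Cd9 (145 and 38.6 CPM) and Cd80 (66.2 and 15.7 CPM). With doublets kept the log2 ratio of Slpi there was -1.40 in place of -2.13. Library 2 had more Rtp4 (10.1 and 52.9 CPM) and Gyg1 (130.0 and 421 CPM).

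Neutrophil-like cells of library 2 had more Hpse, which encodes heparanase (0.795 and 58.4 CPM), Hp (93.1 and 561 CPM), Retnlg (874 and 3620 CPM), Slc2a3, a glucose transporter gene (141 and 412 CPM), Stfa2 (1207 and 3205 CPM), Serpinb1a (594 and 1583 CPM) and Casp1 (55.5 and 154 CPM). Those of library 1 had more Siglec5 (228 and 21.6 CPM), Cd244 (57.0 and 2.99 CPM), Thbs1 (79.5 and 9.50 CPM), Ltb4r (209.8 and 47.0 CPM), Bcl2a1, a survival gene (3234 and 1082 CPM), and Ccl2 (771 and 259 CPM). Clusters 0 and 5 hold most of the class in library 1 and library 2, and Retnlg and Stfa2 lead cluster 5. As a mean over clusters, the log2 ratio of Retnlg was 0.64, of Hp 1.22, of Slc2a3 0.65, of Serpinb1a 0.43, of Thbs1 -1.44, of Bcl2a1 -0.97 and of Ccl2 -0.33.

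In NK-like cells library 2 had more Pi16 (2.16 and 58.3 CPM), Mcpt1l1 (0.180 and 58.1 CPM), Sept5 (7.01 and 70.1 CPM) and Ccl1 (130.1 and 372 CPM). The log2 ratio of Mcpt1l1, which also leads the mast cell- or basophil-like cluster, was 1.497 with thinning in place of 2.74, and that of Sept5 was 0.73 as a mean over clusters. Sept5 and Ccl1 lead cluster 17, with 38 cells of library 1 and 416 of library 2. Library 1 had more Itga4 (83.4 and 32.6 CPM) and Klrg1 (180.3 and 83.6 CPM), with a log2 ratio for Klrg1 of -0.62 as a mean over clusters in place of -1.02. In T-like cells library 2 had more of the class II genes RT1-Ba (26.8 and 73.4 CPM) and RT1-Da (68.1 and 141 CPM) and of Ly49s6 (56.7 and 163 CPM). With thinning the log2 ratio of RT1-Da was 0.55 in place of 0.95, and 0.127% (0.0154 to 0.457) and 0.796% (0.500 to 1.20) of T-like cells had a UMI of the B cell gene Cd79b (0.691% and 2.21% without thinning). Library 1 had more Fhl2 (104 and 39.8 CPM) and Ckb (153 and 64.6 CPM), and also more of the myeloid transcripts Spp1 (65.9 and 13.2 CPM) and Slpi (74.9 and 18.6 CPM). With doublets kept the log2 ratio in T-like cells was -0.72 for Spp1 in place of -1.71 and -0.95 for Slpi in place of -1.57. In B-like cells library 2 had more Ccl5 (60.0 and 141 CPM) and Nr4a2 (68.5 and 134 CPM), and library 1 more Ccr6 (192 and 97.1 CPM) and Sdc4 (84.9 and 31.3 CPM). With doublets kept the log2 ratio of Ccl5 in B-like cells was 0.09.

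Apoe, a macrophage transcript at 30797 and 18951 CPM in macrophage-like cells, was the gene with the lowest ratio in T-like (409 and 114 CPM), B-like (839.9 and 288 CPM), NK-like (317 and 125 CPM) and conventional dendritic-like cells (463 and 87.1 CPM). With doublets kept, the log2 ratio in conventional dendritic-like cells was 0.55 in place of -2.29. The score cut-off for doublets was 0.2777 in library 1 and 0.2129 in library 2, so mixed cells were not limited alike in both. In monocyte-like cells Apoe stood at 1077 and 1288 CPM. The Y-linked gene Eif2s3y was found in both libraries, with 105 and 93.2 CPM in macrophage-like cells, as was Kdm5d, with 49.5 and 44.6 CPM in B-like cells. Of the Y-linked gene Ddx3y the 7 classes held 0 UMIs in library 1 and, in library 2, 1 UMI in macrophage-like and 1 in NK-like cells, and Usp9y had 0 UMIs in these classes of both libraries. Xist was not measured, so these counts do not show whether cells of female animals were present.

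The type I interferon list was higher in library 2 in all 7 classes, with medians of 0.31 to 1.14 (0.22 in neutrophil-like cells as a mean over clusters). Free RNA of neutrophil-like cells, where Isg15 reached 6169 CPM in library 2, would also bring S100a9, and the amount that S100a9 allows in T-, B-, NK- and macrophage-like cells accounts for at most 0.889% of the level of the list members (median over members), although it could give 23.4 of 83.9 CPM of Isg15 in macrophage-like and 10.1 of 40.5 CPM in B-like cells; an earlier test on the ratio of S100a8 and S100a9 (median 0.07) had decided nothing. Depth or scaling argues poorly too, since the lowest median over 7 classes under TMM and thinning was 0.27, and so does cluster make-up in the T-, NK- and macrophage-like classes, where 9 of 11 clusters had 100 or more cells in each library and 100% of these 9 lay above 0 (0.42 to 0.78), with 0.27 in the smaller cluster 17 and 0.63 in cluster 20, while the B-, monocyte- and conventional dendritic-like classes are 1 cluster each and were not tested for it. In neutrophil-like cells cluster make-up stays open, with medians of 0.50 in cluster 0 and -0.093 in cluster 5. A difference between the animals or between the preparations of these 2 libraries may lie behind the pattern and stays open. The immediate early list was also higher in library 2 in 5 of the classes by 0.13 to 0.32 (0.029 in monocyte-like cells with TMM). Its median was 0.03 in T-like and -0.16 in neutrophil-like cells, where the interferon medians were 0.50 and 0.63. The 2 lists therefore did not move together in every class. No explanation by group was tested.

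Hba-a2 has 2 entries in the annotation, and conventional dendritic-like cells filled mostly 1 of them. With 2 of these cells per library left out for erythroid genes or 50 or more haemoglobin UMIs, the first entry, ENSRNOG00000047321, took 453 of their UMIs in library 1 and 326 in library 2, the other 2 and 10. Free haemoglobin RNA would keep the ratio seen in T-, B-, NK- and neutrophil-like cells, where the first entry took 37.7% (25.6 to 51.0) and 22.2% (17.6 to 27.3), but it took 99.6% (98.4 to 99.9) and 97.0% (94.6 to 98.6) in the dendritic-like cells, also above macrophage-like cells, with 60.4% (51.8 to 68.6) and 63.7% (56.3 to 70.7), and monocyte-like cells, with 70.6% (44.0 to 89.7) and 55.6% (35.3 to 74.5), which lay between. Attached or engulfed erythroid cells would bring beta-globin, of which at most 0.0610 times the number expected from the 3 and 10 erythroid cells was found. Expression of 1 alpha-globin gene in these cells, or reads of another transcript counted under it, could give this, and counts per gene cannot tell these apart. Unnamed cluster 15, also led by Hba-a2, was not part of these counts.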
